A study of Mus musculus with 5 samples.

How the data were processed

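Single-cell RNA libraries of 5 segments of mouse intestine were used, 1 library per segment. Per the labels, cells were stained with 5 µg/ml propidium iodide, negative cells were sorted, and libraries were made on the 10x Genomics platform and sequenced as 150-bp paired-end reads. The deposited matrices hold UMI counts per gene and cell barcode, as whole numbers without normalization, for 32285 genes. The submitters' processing notes name Cell Ranger 4.0.0, Seurat without a version and the mouse build mm10, whereas the header of each matrix names cellranger 7.2.0. The spatial measurements that the study's design text mentions were not analysed here. Gene positions come from a RefSeq annotation of GRCm38.p6, the assembly behind mm10, matched by symbol, and 26335 of the 32285 symbols were found once.

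Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept, which left 12255 of 16535. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 barcodes, 333 in all. Scrublet's automatic threshold marked 29 barcodes and was used as an alternative. The 11922 cells left held 210176116 of 250629913 UMIs. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 (igraph 0.11.9), without batch correction, since each segment is its own library. Stromal clusters of at least 50 cells were divided once more at resolution 0.3 with 10 components, and parts of at least 10 cells were kept. Clusters were named from 30 marker lists. A name needed at least 3 markers raised at least 1.5-fold over the other clusters, with a prior of 5 CPM and detection in at least 10% of cells. Tuft-like cells formed no cluster and were named by at least 4 tuft markers with a UMI. Stromal clusters that met no more specific stromal list were called fibroblast-like, and other clusters without enough markers stayed unnamed. Names carry "like" because they rest on transcripts alone. Several clusters were mostly of 1 library, so their leading genes cannot be separated from that library.

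UMIs were summed per class and library and given as CPM. No test was made between segments. Small (3 libraries) and large intestine (2 libraries) were compared by a rule of size, a gap of at least 4-fold between the lowest library of one side and the highest of the other and at least 50 UMIs in the class. Genes named in the text come from the 10 with the widest gaps in each direction and, for absorptive and stromal cells, the 5 most above the other segments, together with members of the lists, and without mitochondrial, immunoglobulin and T cell receptor genes and unnamed gene models. Counts of 0 were set to a floor of 3 counts. Shares of cells with a Gnai1 UMI were also taken after thinning each cell to 1000 UMIs. For the Gnai1 contrast, stromal cells with a Gnai1 UMI were paired with cells without any by total UMIs within the library, and counts were summed per library. Libraries needed at least 10 cells on each side. Sums were tested with the edgeR 4.0.16 quasi-likelihood test with library as a term, TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05, without Gnai1 itself. The named genes of this contrast were those past the threshold and changed the same way in every library. Its p-values measure the spread between these libraries.

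There were 16 gene lists: goblet and mucus, Paneth, c-Jun and AP-1, JNK, immediate early and dissociation, G alpha, WNT and R-spondin, BMP, niche ligands, Notch and secretory fate, small and large intestinal absorption, posterior HOX, MHC II and interferon, extracellular matrix, and red cell genes. These lists, the marker lists, the filters, the joint clustering, the rule of size, the rule for named genes and the comparisons were fixed before the data were examined. The second division of stromal clusters, the thresholds for naming a cluster and the naming of tuft-like cells were set with the data in hand. A list of 19 interferon-stimulated genes was added later, as were the settings that leave out rectum (absorptive cells), jejunum (stromal cells), or duodenum and jejunum (goblet cells), that leave out the PDGFRA-high class, that use colon and rectum alone, or that leave Paneth and defensin genes out of the UMI totals of Paneth-like and absorptive-like cells.

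The alternatives fixed in advance were every deposited barcode kept, at most 10% mitochondrial UMIs, at least 1000 genes, no doublets removed, Scrublet's own threshold, Leiden resolutions of 2 and 0.5, and each library clustered on its own. Further ones were the mean over cells of each cell's fractions, CPM with TMM factors, thinning to 2000 UMIs, gaps of 2-fold, a minimum of 200 UMIs, and removal of genes whose share in immune cells exceeded 10% of that in the class. The Gnai1 contrast was also run with DESeq2 1.42.0, without a filter, against all stromal cells without a UMI, with pairs matched within stromal clusters, and without each library in turn. Both methods were tested on simulated data. With 200 changed genes the Gnai1 contrast recovered 69 of 100 at 2-fold and 88 of 100 at 4-fold, and called 7 unchanged genes. The rule of size recovered 92, 100 and 92 of 100 genes at 8-fold in absorptive, goblet and stromal cells and 0 at 2-fold, with 0 unchanged genes passing. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.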

Results

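Messenger RNA was counted in single cells of mouse intestine by droplet sequencing on the 10x Genomics platform. There were 5 libraries, 1 each from duodenum, jejunum, ileum, colon and rectum, so no segment was replicated. The labels list epithelial, mesenchymal and immune cells, and live cells had been sorted as negative for propidium iodide, a dye that enters dead cells. The study concerns stromal cells that express Gnai1, the gene of an inhibitory G-protein alpha subunit, and how they bear on goblet and Paneth cells by way of the transcription factor c-Jun. The libraries held 4355, 2884, 3342, 2926 and 3028 barcodes in the order from duodenum to rectum, which is the order of all values given by segment. Their total UMI counts were 65546664, 44726663, 41953568, 53738965 and 44664053. After filtering, 3196, 1829, 2455, 2148 and 2294 cells were kept, with median UMIs per cell of 5059, 9767, 5485, 9270 and 8886. Levels are CPM of the summed UMIs of the cell class. All 95% intervals are exact (Clopper-Pearson for shares, Poisson for CPM) and, like the limits from counts of 0, cover counting error only.

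The first comparison asked which cell classes each segment yielded. Immune and epithelial cells made up most of every library, and stromal cells were a small share that was higher in colon and rectum. Absorptive cells dominated the epithelium of duodenum and jejunum, whereas crypt cells, which hold the stem and dividing cells, were the largest epithelial class of the rectum after filtering. With every deposited barcode kept, rectal absorptive-like cells outnumbered crypt-like cells, at 43.3% (622 of 1437) against 32.8% of the epithelium. The immune share was 63.6%, 54.4%, 53.0%, 38.5% and 51.4% of cells kept, and B-like cells alone made up 39.3%, 28.4%, 37.4%, 18.9% and 22.8%. Plasma-like cells, the antibody-secreting B lineage, were highest in rectum at 10.9%, against 1.43% to 4.98% elsewhere. T-like cells were highest in duodenum at 10.0%, with 3.12% to 5.47% in the other libraries. The epithelial share was 34.0%, 43.6%, 45.4%, 52.4% and 34.4%. Stromal cells numbered 52, 13, 23, 169 and 286, or 1.63%, 0.711%, 0.937%, 7.87% and 12.5%. The lowest stromal share of the large intestine exceeded the highest of the small intestine by 6.24 percentage points, and by 9.59 points when cells above 10% mitochondrial UMIs were removed. Fibroblast-like cells, the name given to stromal clusters without a more specific one, made up 34.6% to 56.2% of stromal cells. They include a cluster with 23 colonic cells and the trophocyte marker Ackr4 among its leading genes. Trophocyte-like cells, the deep-lying fibroblasts that secrete Grem1, were 17.3%, 46.2%, 56.5%, 21.9% and 14.0% of them. Cells of the PDGFRA-high class, named from markers of the subepithelial fibroblasts also called telocytes, were 28.9%, 0, 4.35%, 14.2% and 26.6%. Pdgfra itself was not among those markers. Shares of classes reflect the sort, the mitochondrial filter and dissociation as well as the tissue.

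Goblet and Paneth cells are the secretory cells on which the study centres. Goblet-like cells, which make mucus, formed a small share of the epithelium in duodenum and jejunum and a larger share in ileum, colon and rectum. Paneth-like cells, which secrete defensins and lysozyme at the crypt base, were found in the 3 small intestinal libraries alone, and most of them were ileal. Goblet-like cells were 4.24% of epithelial cells in duodenum (interval 3.12% to 5.61%), 4.26% in jejunum (2.97% to 5.90%), 22.6% in ileum (20.2% to 25.2%), 34.3% in colon (31.5% to 37.1%) and 30.8% in rectum (27.6% to 34.2%). Different clusters held the class in different segments. Those of the small intestine were led by Zg16, Fcgbp and Tff3, those of the colon by Reg4, Retnlb and Muc2 in 289 cells and by Plet1, Muc2 and Nxpe2 in 97, and those of the rectum by Sval1, Mptx1 and Best2. The lowest goblet share of the large intestine exceeded the higher of duodenum and jejunum by 26.5 percentage points. With every deposited barcode kept the gap was 17.0 points, with each library clustered on its own it was 3.21, and with at most 10% mitochondrial UMIs it turned to -15.5. Ileum exceeded the higher of duodenum and jejunum by 18.4 points, or by 12.2 with every barcode kept. Paneth-like cells numbered 8, 4 and 24, or 0.737% (0.319% to 1.45%), 0.501% (0.137% to 1.28%) and 2.15% (1.39% to 3.19%) of epithelial cells. None was found among 1126 colonic and 789 rectal epithelial cells, which allows shares of up to 0.327% and 0.466% by the upper bounds of the intervals. The ileal Paneth excess of 1.42 points turned to -11.4 when each library was clustered on its own. Absorptive-like cells were 57.2%, 77.7%, 27.8%, 24.0% and 7.22% of the epithelium (the last 43.3% with every barcode kept), and crypt-like cells 34.5%, 15.2%, 19.9%, 36.5% and 59.8%. A further 25.0% of ileal epithelial cells stayed unnamed, in a cluster led by the antimicrobial lectins Reg3g and Reg3b and by the bile acid carrier Fabp6. Fabp6 and Naaladl1 were among the leading genes of both this cluster and the ileal absorptive-like cluster, so the unnamed cells may include absorptive ones. The ileal absorptive-like share and all ileal absorptive-like levels leave them out. Enteroendocrine-like cells, the hormone-secreting class, were 1.25% to 4.71%, and tuft-like cells 0.127% to 0.921%. The mitochondrial filter left 57 rectal absorptive-like cells with a median of about 5288 UMIs in their main cluster, far below the 32032 of the colonic cluster.

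**Figure D1:**
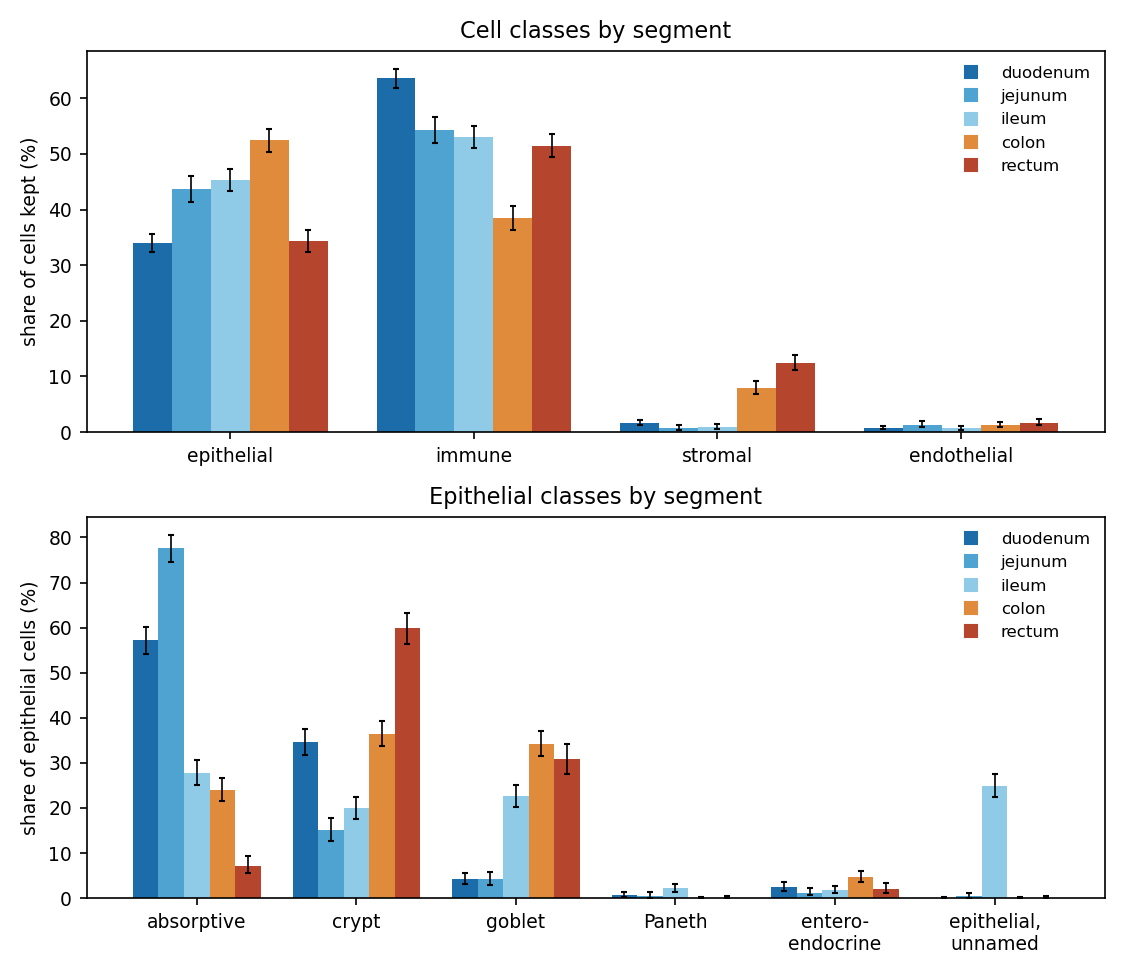
Bars show the share of cells kept (%, upper panel) and of epithelial cells (%, lower panel) by cell class, coloured by segment with 1 library each, and error bars are 95% Clopper-Pearson intervals. Stromal shares reach 7.87% and 12.5% in colon and rectum, and goblet-like shares reach 34.3% and 30.8% there.

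The level of Gnai1 (ENSMUSG00000057614, chromosome 5, 18265135 to 18360413 in mm10) was compared between cell classes and segments, since the study defines its stromal cells by this gene. Gnai1 was far higher in stromal than in immune cells of every library. Within the stroma its UMIs concentrated in the PDGFRA-high class in duodenum (35 of 62), colon (88 of 129) and rectum (287 of 396), and in the sum over libraries. In ileum trophocyte-like cells held 14 of 22 and the 1 PDGFRA-high cell 6, and jejunum had no PDGFRA-high cell. In stromal cells it reached 145 CPM in duodenum (interval 111 to 186), 36.2 in jejunum (9.86 to 92.7, from 4 UMIs), 101 in ileum (63.3 to 153), 104 in colon (87.2 to 124) and 161 in rectum (145 to 177). The intervals of duodenum, ileum and colon overlapped. That of rectum overlapped those of duodenum and ileum, and that of jejunum overlapped those of ileum and colon. Summed over the 5 libraries, PDGFRA-high cells held 443 CPM, smooth muscle-like cells 111, fibroblast-like cells 54.9 and trophocyte-like cells 37.3. The order of the last 2 varied, with 80.4, 64.8, 35.7, 39.7 and 60.4 CPM by segment in fibroblast-like cells and 96.0, 0, 91.8, 6.47 and 32.7 in trophocyte-like cells. The PDGFRA-high class supplied 416 of 613 stromal Gnai1 UMIs, and 93 of its 116 cells (80.2%) had at least 1. Gnai1 was among the 10 leading genes of 1 of the 3 PDGFRA-high clusters, with 54 of the 116 cells, but with Gnai1 left out of clustering and naming, a setting chosen after the data were seen, the class held the same 116 cells and 67.6% of stromal Gnai1 UMIs. By segment this class held 272 CPM in duodenum, 513 in colon and 456 in rectum. Immune cells, which served as background, held 0.237 CPM and endothelial cells 2.32. A Gnai1 UMI was found in 57.7%, 23.1%, 43.5%, 26.6% and 47.9% of stromal cells, at median depths of 8273, 9744, 9440, 7219 and 8872 UMIs. In immune cells the share was 0.0492%, 0, 0.154%, 0.605% and 0.0848%, at median depths of 3556, 4201, 3641, 3267 and 4685. With every cell thinned to 1000 UMIs the stromal shares were 11.8% (6 of 51 cells), 0 of 12, 0 of 22, 7.74% (13 of 168) and 10.3% (29 of 283), with 1, 1, 1, 1 and 3 shallower cells left out. The related genes Gnai2, at 308 to 519 CPM, and Gnas, at 922 to 1104 CPM, were higher than Gnai1 in the stroma of every segment, and Gnai3 lay at 98.7 to 124. None of the 10 G alpha genes met the size rule between small and large intestine over whole libraries.

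**Figure D2:**
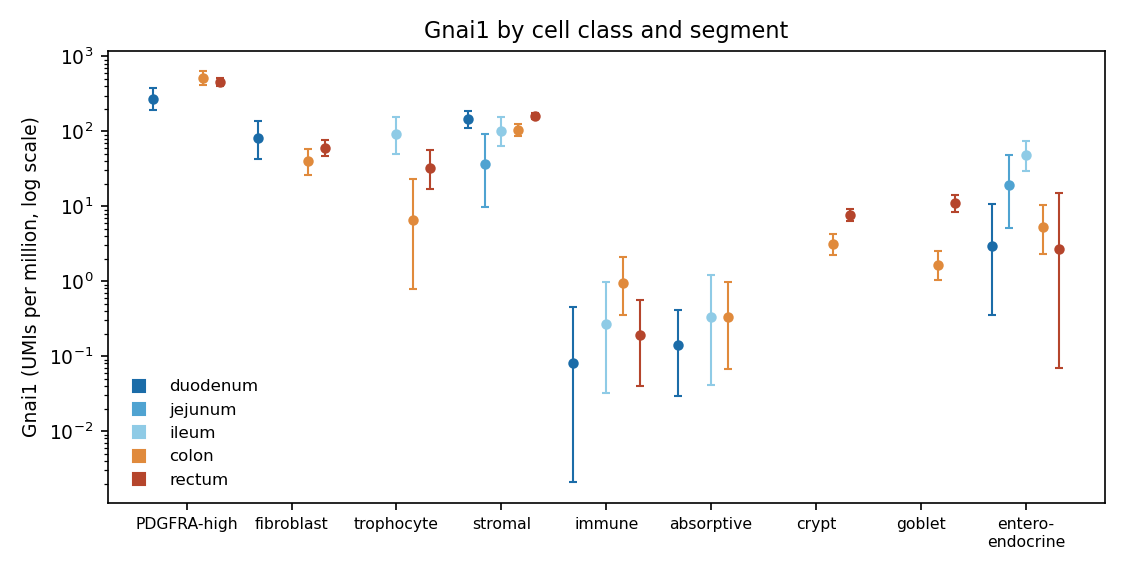
Points show Gnai1 in CPM (log axis) by cell class, coloured by segment with 1 library each, and error bars are 95% Poisson intervals. Classes with under 10 cells or no Gnai1 UMI are not drawn, and the PDGFRA-high class lies highest, at 272 to 513 CPM.

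Stromal cells with a Gnai1 UMI were compared with stromal cells of the same library without any, matched on total UMIs, to ask what else marks them. The cells with Gnai1 carried more osteoglycin (Ogn), a small leucine-rich proteoglycan of the matrix, and more Col4a5, a basement membrane collagen chain. They also leaned toward the PDGFRA-high class, whose BMP and WNT ligands pattern the crypt-villus axis. In this contrast libraries served as replicates, and the spread between them includes the difference between segments. It used 4 libraries with 22, 10, 45 and 137 matched pairs in duodenum, ileum, colon and rectum, and jejunum was left out with 3 pairs. Of 4328 genes tested by edgeR with Benjamini-Hochberg adjustment, 2 were higher and 0 were lower in cells with Gnai1, with 305 genes at an unadjusted p under 0.05. DESeq2 called 6 higher and 2 lower. Ogn (ENSMUSG00000021390, chromosome 13, 49608015 to 49624501) rose by a log2 fold of 1.24 (SE 0.14, edgeR Benjamini-Hochberg adjusted p 0.0378) and was higher in 4 of 4 libraries. Its CPM went from 1105 to 3072 in duodenum, 655 to 1546 in ileum, 606 to 1642 in colon and 1371 to 2636 in rectum. Col4a5 (ENSMUSG00000031274, chromosome X, 141475370 to 141689236) rose by 1.73 (SE 0.22, edgeR Benjamini-Hochberg adjusted p 0.0427), also in 4 of 4 libraries. Its CPM went from 42.3 to 95.3, 29.8 to 81.9, 62.0 to 192 and 47.4 to 200. In edgeR 0 genes passed without the colon library (81 at an unadjusted p under 0.05), without the rectum library (105), with at most 10% mitochondrial UMIs (277), or with the PDGFRA-high class left out (73), a setting chosen after the data were seen. DESeq2 was not run in these settings. The log2 fold of Ogn stayed at 1.19, 1.36 and 1.15 in the first 3 of these, whereas without the PDGFRA-high class it was 0.26. Without duodenum 19 genes were higher and 12 lower, and without ileum 19 and 18. PDGFRA-high cells were 8 of the cells with Gnai1 against 4 of those without in duodenum, 1 against 0 in ileum, 20 against 1 in colon and 61 against 12 in rectum. When pairs were matched within stromal clusters, which left 3 libraries, the log2 folds of Ogn and Col4a5 were 0.19 and 0.21 and neither passed.

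Gene lists fixed beforehand were used to ask which signalling genes went with Gnai1. Over all genes tested, Col4a5 was the only list member past the threshold, and the counts that follow were adjusted over the list alone. Of the genes past that threshold Bmp5, Bmp7, Sox6, Pdgfra, Col4a5, Maff, Nr4a1 and Hspa1a went the same way in 4 of 4 libraries. The others did so in 3 of 4. The folds given here come from pairs not matched within stromal clusters, so a difference in the mix of classes stays open for them. PDGFRA-high cells were more frequent among cells with Gnai1, at 20 against 1 in colon and 61 against 12 in rectum. Bmp5, Bmp7, Wnt5a, F3 and Sox6 are on the marker list that named this class. Their higher values therefore do not show that they go with Gnai1 within a class. Among 7 BMP genes and antagonists 4 ligands were higher, namely Bmp3 (log2 fold 2.93), Bmp7 (1.74), Bmp5 (1.20) and Bmp2 (0.71), whereas Bmp4 (0.14), Bmp6 (-0.13) and the antagonist Grem1 (-0.64) did not pass. Among 6 WNT and R-spondin genes Wnt5a (1.33) was higher, and among 7 niche ligands the EGF-family ligand Ereg (1.06) was higher and the alarmin Il33 (-1.05) was lower. All 5 markers of PDGFRA-high cells that were tested were higher, namely Sox6 (2.77), F3 (1.41) and the Bmp5, Bmp7 and Wnt5a already counted above, and so was 1 of 9 fibroblast markers, Pdgfra (0.68). Cd81 (-1.11) was lower among 5 trophocyte markers. Of 7 smooth muscle markers and 2 pericyte markers 0 passed. The c-Jun and AP-1 list leaned lower, with 3 of 8 members past the threshold, namely Maff (-1.11), Fosl2 (-0.73) and Junb (-0.57). Jun itself did not pass, at -0.08. In the dissociation list 3 of 12 were lower, namely Nr4a1 (-1.33), Hspa1a (-0.94) and Dnajb1 (-0.80). Trophocyte-like cells were 5 of the cells with Gnai1 against 2 of those without in duodenum, 7 against 5 in ileum, 2 against 17 in colon and 8 against 30 in rectum. In colon and rectum that class carried 8419 and 9894 CPM of the AP-1 list, against 2027 and 2213 in PDGFRA-high cells. In the extracellular matrix list 1 of 17 was higher, Col4a5. The lists of G alpha genes (7 tested), Notch and secretory fate (2), goblet and mucus (2), Paneth (1), JNK (1), posterior HOX (1), small (3) and large (2) intestinal absorption and MHC II (1) had 0 members past the threshold.

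Absorptive cells of the small and large intestine were compared to show how far the libraries separate known regional functions. Small intestinal cells carried the brush-border enzymes that finish digestion of sugars and peptides, sucrase-isomaltase (Sis), lactase (Lct) and aminopeptidase N (Anpep), together with the lipoprotein gene Apoa1. Large intestinal cells carried carbonic anhydrase 1 (Car1), the acute-phase gene Saa1 and the amino acid transporter Slc6a14. Absorptive-like cells of duodenum with jejunum, of ileum, of colon and of rectum lay almost wholly in separate clusters, named from a list of small intestinal enterocyte or of colonocyte markers. Sis, Lct, Anpep, Apoa1, Car1 and Saa1 are on these lists, so their side is in part fixed by the naming. No test was made, since the libraries of each side are different segments and not replicates, so genes were taken by a rule of size, under which the lowest value of one side had to exceed the highest of the other by at least 4-fold, with at least 50 UMIs. Of 10292 genes, 227 were higher in the small and 258 in the large intestine by this rule. Values did not overlap for 19.8% and 22.7% of genes, where chance gives 10% in each direction for 3 against 2 libraries. The smallest two-sided exact permutation p of such a design is 0.2. Sis (ENSMUSG00000027790, chromosome 3, 72888557 to 72967863) stood at 2091, 3275, 3332, 19.1 and 0 CPM, a gap of 109-fold. Anpep stood at 1953, 2734, 4174, 19.1 and 0 CPM, and Apoa1 at 7832, 14220, 18290, 83.2 and 1.96 CPM. The gap of Tm4sf5 was 104-fold, and those of Lgals2 and Reg3a were 67.6-fold and 56.8-fold. Anxa13 was at least 71.3-fold higher and Lct at least 61.2-fold. Fbln1 stood at 140, 222 and 121 CPM against 1.11 and 1.96. On the large intestinal side Car1 (ENSMUSG00000027556, chromosome 3, 14766214 to 14808365) stood at 46140 CPM in colon and 5132 in rectum and had no UMI in the small intestine, at least 10120-fold. Slc6a14 was at least 340-fold higher. Saa1 stood at 286 and 5136 CPM, with 1 UMI in the small intestine, and the sialyltransferase St6galnac6 stood at 116 and 317. Fa2h, which hydroxylates sphingolipids, stood at 189 and 96.0 CPM, Mal at 388 and 155, Sult1a1 at 450 and 45.1, Hao2 at 538 and 174, Mboat1 at 122 and 194, and Hk1 at 74.3 and 114. The counts moved with the settings. At 2-fold they were 565 and 597. With genes removed whose share in immune cells exceeded 10% of that in the class in any library they were 91 and 38. Of the 10 largest gaps 6 then remained on each side, without Anpep, Tm4sf5, Lgals2 and Fbln1 on the small and St6galnac6, Sult1a1, Mboat1 and Hk1 on the large intestinal side. This rule also covers the side where a gene is low, so the gap itself removes genes, and the fall does not measure free RNA. Anpep stood at 44.05% in colon but at most 2.325% in small intestine. Tm4sf5, Fbln1, St6galnac6 and Mboat1 also failed on their low side alone. Lgals2, Sult1a1 and Hk1 exceeded 10% on their high side as well. With the rectum library left out the counts were 474 and 444. At most 10% mitochondrial UMIs gave 109 and a minimum of 200 UMIs gave 162 on the large intestinal side.

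Each segment also had genes of its own in absorptive cells. Duodenum led for the sulfotransferase Sult6b2 (109 CPM, 14.8-fold over the next segment), Ifitm3 (5.20-fold), Reg1 (1263 CPM, 5.02-fold), Nr4a2 and Spc24. Jejunum led for Pfkfb3 (2.67-fold), the vitamin C transporter Slc23a1 (2.06-fold), Lct (2.05-fold), Slc7a8 (2.02-fold) and Ccl27a. Ileum led for the bile acid genes, with Fabp6 at 51100 CPM (250-fold) and Fgf15 at 313 CPM (32.3-fold), and for Plb1 (685 CPM), Suox and Map3k6. The ileal bile acid transporter Slc10a2 stood at 329 CPM in ileum. Colon led for Gal3st2c (315 CPM), Sult1c2, Cwh43 and Retnlb, which is a goblet gene. Rectum led for Tgm3 (2811 CPM), Fxyd4 (1099 CPM), the proton pump Atp12a (903 CPM), Hoxb13 (778 CPM) and Ly6g (343 CPM). Of 23 small intestinal absorption genes 14 met the rule on the small intestinal side, and the iron exporter Slc40a1 alone met it on the other (5.46-fold). Of 20 large intestinal absorption genes 9 met it on the large intestinal side, and so did Hoxa7 and Hoxb9 among 7 posterior HOX genes. Cyp2c55 stood at 47.0, 41.1, 23.3, 4737 and 768 CPM, and Aqp8 at 45.9, 4.34, 0.169, 586 and 676 CPM. Gata4, a regulator of proximal identity, stood at 62.9, 58.9, 28.1, 0.442 and 0 CPM. Of the MHC II and interferon list 0 of 10 met the rule, yet Reg3b reached 1909 CPM in ileum against 126 in duodenum and 189 in colon.

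**Figure D3:**
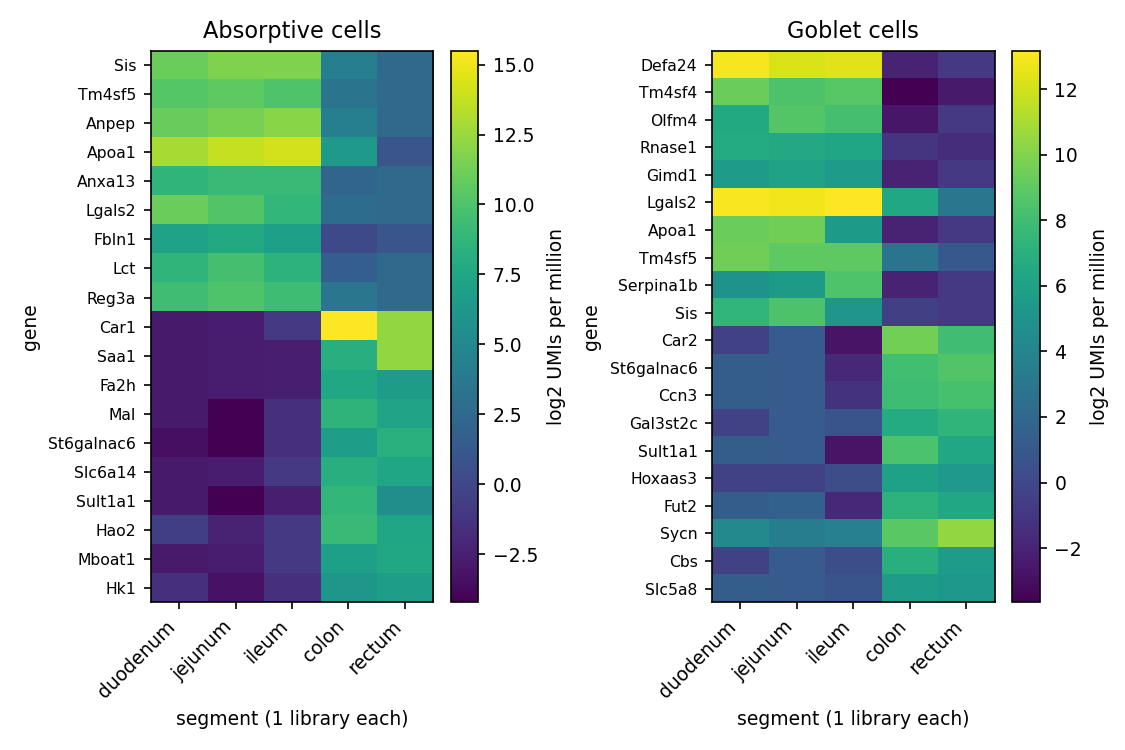
Heat maps show the log2 of CPM by segment (1 library each, horizontal axis) for genes among those with the widest gaps between small and large intestine (vertical axis) in absorptive-like and goblet-like cells. Counts of 0 are drawn at a floor of 3 counts, and Car1 and Defa24 are examples with no UMI on one side.

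Goblet-like cells were compared between small and large intestine because they are a target cell of the study. Small intestinal goblet cells carried more of the lectins Itln1 and Zg16 and the trefoil peptide Tff3, and UMIs of genes typical of Paneth cells and enterocytes were counted in them too. Large intestinal goblet cells carried carbonic anhydrase 2 (Car2), the matricellular gene Ccn3 and the fucosyltransferase gene Fut2. Of 10651 genes 116 were higher in the small and 99 in the large intestine by the size rule, with 9.66% and 32.8% not overlapping against 10% by chance. The class held 46, 34, 252, 386 and 243 cells. Defa24 (ENSMUSG00000064213, chromosome 8, 21734494 to 21735471) stood at 7749, 4825 and 5408 CPM in the small intestine and had no UMI in the large, at least 8829-fold, and it is a defensin of Paneth-like cells. Tm4sf4 stood at 681, 348 and 444 CPM, the stem cell gene Olfm4 at 94.0, 410 and 291, Rnase1 at 103, 89.8 and 80.6, Gimd1 at 51.0, 65.3 and 50.7, and Serpina1b at 30.8, 46.0 and 367. Each of these had under 1 CPM in the large intestine. The enterocyte genes Lgals2 (86.7-fold), Apoa1 (644.9, 724 and 45.4 CPM), Tm4sf5 (74.6-fold) and Sis (173, 358 and 35.2 CPM) were among the widest gaps. In immune cells of the same libraries, which hold free RNA, Apoa1 reached 78.1% of its goblet level in ileum, Olfm4 51.3% in jejunum and Sis 30.4% in ileum, against at most 2.04% for Defa24. These are ratios of CPM, and immune cells were shallower, at an ileal median of 3641 UMIs against 30986 in goblet-like cells. Free RNA adds about alike to every droplet, so these ratios overstate what it could supply to a goblet-like cell. Genes were then removed whose share in immune cells exceeded 10% of that in the class in any library. Of the 10 widest gaps on the small intestinal side 4 remained, namely Defa24, Gimd1, Lgals2 and Serpina1b, and on the other side 3, namely Ccn3, Gal3st2c and Fut2. Of the genes removed, Olfm4, Apoa1, Sis and, on the other side, Sult1a1 exceeded 10% on their high side. The others failed only where they are low, so through the gap itself. Tm4sf4, for example, stood at 140.7% in rectum but at most 0.6296% in small intestine. Car2 was at least 116-fold higher in the large intestine (760 and 259 CPM), St6galnac6 at least 114-fold and Ccn3 at least 103-fold. Gal3st2c stood at 102 and 161 CPM, Sult1a1 at 335 and 81.8, Hoxaas3 at 61.6 and 41.7, and Slc5a8 at 47.7 and 39.5. Fut2 had a gap of 27.3-fold, Sycn of 23.6-fold and Cbs of 21.1-fold.

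In the goblet and mucus list 3 of 21 genes met the rule on the small intestinal side, Itln1 (22.8-fold), Zg16 (4.97-fold) and Tff3 (4.69-fold), and Muc4 (6.97-fold) on the other. Zg16 (ENSMUSG00000049350, chromosome 7, 127050156 to 127052675) stood at 71900, 53720, 74330, 3239 and 10810 CPM. Tff3 stood at 39920, 33350, 37890, 1707 and 7108, and Fcgbp at 21740, 17570, 9473, 561 and 2545. The gel-forming mucin Muc2 (ENSMUSG00000025515, chromosome 7, 141690340 to 141754691) showed no such split, at 7892, 8431, 9920, 20830 and 6449 CPM. Retnlb was highest in colon at 17210 CPM, and Mptx1 in rectum at 17660. Of 12 Paneth genes 6 met the rule on the small intestinal side, among them Defa17 (47.5-fold), Defa30 (44.5-fold), Mmp7 (21.1-fold) and Lyz1 (18.7-fold). Of 19 small intestinal absorption genes 5 did so. Among 19 large intestinal absorption genes Slc5a8 and Car1 (4.42-fold) were among those that met it on the large intestinal side, and Krt20 (12.7-fold) on the small. Hoxa7 (6.33-fold) and Hoxb9 (5.27-fold) did so among 13 posterior HOX genes, and Hoxb13 stood at 350 CPM in rectum with no UMI elsewhere. None of 11 Notch and secretory fate genes met the rule. Atoh1, which commits cells to the secretory lineage, stood at 171, 136, 260, 195 and 310 CPM, and Spdef at 164, 216, 182, 417 and 139. The Notch ligand Dll1 stood at 160, 130, 99.5, 15.1 and 52.7. The count on the small intestinal side was 12 with at most 10% mitochondrial UMIs and 70 at a minimum of 200 UMIs. At 2-fold the counts were 237 and 328. With genes removed by their share in immune cells they were 28 and 19, a fall that the gap itself partly brings about. With duodenum and jejunum left out the count on the large intestinal side was 301.

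Stromal cells were compared between small and large intestine over fibroblast-like, trophocyte-like and PDGFRA-high cells together (42, 11, 22, 156 and 255 cells). Small intestinal stroma carried more Lrat, which stores retinol as esters, and more Dkk2, a secreted WNT antagonist. No gene met the size rule on the large intestinal side, and the widest gaps there were those of Anxa3, the homeobox gene Prrx2 and the lipid carrier Apod. Of 8133 genes 6 were higher in the small and 0 in the large intestine, with 12.2% and 12.5% not overlapping against 10% by chance. Lrat (ENSMUSG00000028003, chromosome 3, 82892582 to 82903974) stood at 174, 430, 175, 6.90 and 0.447 CPM, a gap of 25.2-fold. Dkk2 (ENSMUSG00000028031, chromosome 3, 132085266 to 132180304) stood at 126, 140, 64.6, 2.59 and 2.23 CPM. Cyp1b1 (7.76-fold), the pericyte marker Rgs5 (7.10-fold), Angptl1 (5.19-fold) and Vldlr (4.66-fold) completed the 6, and Hmcn1 (3.82-fold), Tnfaip3 (3.09-fold), Egflam (3.0-fold) and Myorg (2.92-fold) came next. On the other side Anxa3 (at least 2.73-fold), Nit1 (2.50-fold), Prrx2 (2.43-fold), Gdpd3 (2.35-fold), Hsf2 (2.32-fold), Apod (at least 2.27-fold), Pole4 (2.24-fold), Ppp1r35 (2.21-fold), Lrrc42 (2.05-fold) and Tmem100 (1.93-fold) led. Anxa3 and Apod had no UMI in jejunum, so their folds are set by its floor. With jejunum left out, a setting chosen after the data were seen, the counts were still 6 and 0. At 2-fold the counts were 24 and 9, and at a minimum of 200 UMIs 1 gene remained on the small intestinal side. With no doublets removed 5 genes were higher in the large intestine, and 6 with Scrublet's own automatic threshold. Among 11 WNT and R-spondin genes Dkk2 alone met the rule, and the WNT antagonist Sfrp1 stood at 1627, 1961, 1135, 878 and 531 CPM. None of 8 BMP genes, 10 niche ligands or 19 extracellular matrix genes did. Bmp4 stood at 1057, 340, 258, 678 and 1192 CPM, its antagonist Grem1 at 466, 690, 747, 379 and 131 (sums over classes whose mix differs by segment, with few PDGFRA-high and many trophocyte-like cells in jejunum and ileum), and the chemokine Cxcl12 at 1614, 1181, 798, 1439 and 1453.

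Single segments differed in part through genes of other cell types. The genes most above the other segments in duodenal stroma were the B-cell genes Cd74 (782 CPM, 7.11-fold), H2-Ab1 (5.99-fold), H2-Aa (5.62-fold), Ly6d (4.01-fold) and Cd79a (3.48-fold). In colonic stroma the colonocyte gene Car1 led (12.6-fold), followed by Ctla2a (5.47-fold), Ces1d (5.44-fold), the WNT antagonist Sfrp4 (3.13-fold) and Car8 (2.83-fold). Ileal stroma led for Sult1e1 (10.9-fold), Myc (5.99-fold), Ifi207 (5.69-fold), the interferon-induced chemokine Cxcl10 (5.07-fold) and Lhfpl2 (4.74-fold). Jejunal stroma, with 11 cells, led for Spock2 (9.30-fold), Pfkfb3 (8.88-fold), Stk35 (7.23-fold), Chodl (6.92-fold) and Plce1 (6.15-fold). Rectal stroma led for Stmn2 (2.57-fold), Apod (2.43-fold), Hoxa11os (2.34-fold), Rcan2 (2.26-fold) and Isl1 (1.98-fold). The sum of the AP-1 list in fibroblast-type cells was 4377, 16120, 9178, 4030 and 3522 CPM, and that of the dissociation list 4874, 12420, 8025, 4238 and 4372, so both were highest in jejunum and ileum. Trophocyte-like cells, 6 of 11 and 13 of 22 of these cells, held 14500 and 11820 CPM of the AP-1 list there, and fibroblast-like cells 18000 in jejunum (5 cells) and 2371 in ileum.

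Genes of c-Jun, its AP-1 partners and the JNK pathway were followed across classes because the study names c-Jun signalling. Jun (ENSMUSG00000052684, chromosome 4, 95049036 to 95052222) was somewhat higher in goblet-like than in absorptive-like cells of 4 of 5 libraries, with the widest gap in rectum. Its partner Fosb was higher in goblet-like cells of every library, and Fosl2 was lower in every library. In Paneth-like cells the direction depended on whether defensin UMIs were counted in the total. Jun stood at 1312, 888, 1377, 1279 and 2044 CPM in goblet-like cells and at 1072, 982, 889, 826 and 496 in absorptive-like cells. The goblet over absorptive folds of Jun were 1.22 (interval 1.16 to 1.29), 0.904 (0.852 to 0.959), 1.55 (1.5 to 1.60), 1.55 (1.51 to 1.59) and 4.12 (3.64 to 4.69). With at most 10% mitochondrial UMIs they turned in 3 libraries, to 1.43 in jejunum, 0.890 in colon and 0.601 in rectum. The main rectal goblet cluster stayed unnamed in that setting. The rectal value there thus rests on the few cells that kept the goblet name and does not show a reversal in rectal goblet cells. Fosb folds were 1.88, 1.41, 2.01, 3.09 and 15.9, and Fosl2 folds 0.610, 0.354, 0.289, 0.716 and 0.270. Fos folds were 1.17, 0.908, 1.81, 1.76 and 4.90, and Atf3 folds 0.748, 0.624, 1.56, 2.44 and 10.5. The rectal folds rest on 57 absorptive-like cells, in a library where the mitochondrial filter removed most cells of that class. Of 8 AP-1 genes measured in every library 1 was higher and 1 lower in goblet-like cells of all 5. Of 8 JNK pathway genes 4 were higher in all 5, namely Mapk9, Map2k7, Map3k5 and Dusp1, and 0 were lower. The interval reached 1 for Mapk9 in duodenum, jejunum and rectum, for Map2k7 in jejunum, ileum and rectum and for Map3k5 in rectum, and stayed above 1 in every library for Dusp1 alone. Map3k5, which encodes the stress kinase ASK1, had folds of 5.29, 2.31, 2.48, 2.91 and 2.19. Of 11 dissociation genes 3 were higher in all 5, namely Ier2, Ier3 and Hsp90aa1, and 0 were lower, though the interval reached 1 for Ier3 in duodenum and jejunum and for Hsp90aa1 in duodenum.

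In Paneth-like cells of the 3 small intestinal libraries 7 of 8 AP-1 genes had lower CPM and 0 higher than in absorptive-like cells. With Paneth and defensin genes (28 genes, 71.7%, 76.8% and 77.8% of Paneth UMIs) left out of the totals, a setting chosen after the data were seen, 5 of 8 were higher and 2 lower, and the Jun folds turned to 2.10, 2.32 and 2.90. By CPM the Jun folds were 0.593, 0.539 and 0.645, and Junb folds 0.211, 0.0999 and 0.20. Of 5 JNK genes 3 were lower and 1 higher, and of 10 dissociation genes 6 were lower and 1 higher, the orphan receptor gene Nr4a1 with folds of 15.1, 14.0 and 9.78. Without defensin UMIs 2 JNK genes were higher and 1 lower, and 4 dissociation genes were higher and 1 lower. Defensins take a large part of the UMIs of these cells and so lower the CPM of every other gene. Defa24 alone held 317300, 333500 and 237500 CPM and Defa30 227700, 234200 and 250500, while Lyz1 (ENSMUSG00000069515, chromosome 10, 117287795 to 117292868) held 37600, 34350 and 54400. In crypt-like cells 0 of 8 AP-1 genes were higher and 2 were lower than in absorptive-like cells of all 5 libraries. Of 8 JNK genes 2 were higher and 2 lower, and of 11 dissociation genes 3 were higher and 0 lower. Jun stood at 1115, 800, 709, 1352 and 2012 CPM there. The AP-1 list summed to 5261, 3970, 6204, 4808 and 8526 CPM in goblet-like cells and to 4596, 4421, 4256, 3093 and 3061 in absorptive-like cells. In absorptive-like cells 7 of 9 AP-1 genes were higher in every small than in every large intestinal library, and none met the size rule.

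**Figure D4:**
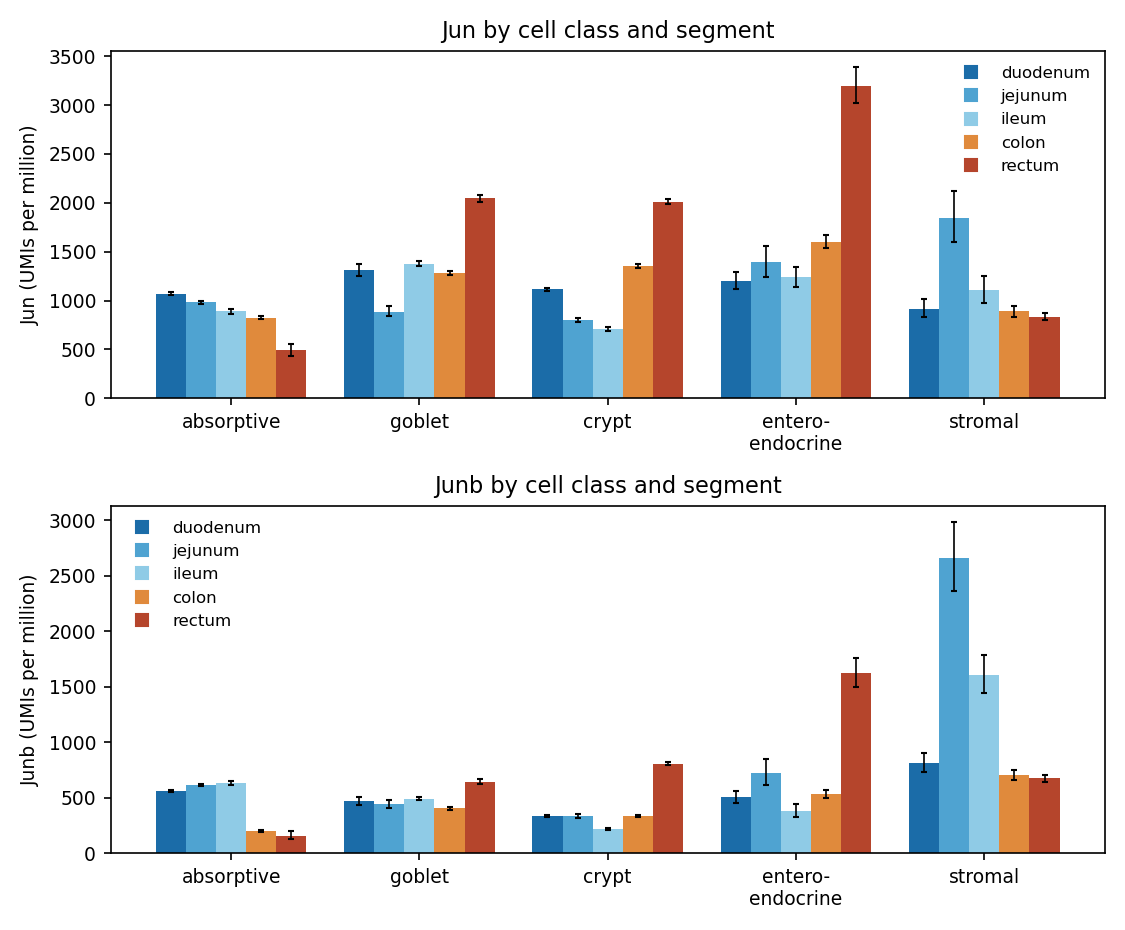
Bars show Jun (upper panel) and Junb (lower panel) in CPM by cell class, coloured by segment with 1 library each, and error bars are 95% Poisson intervals. Jun reaches 2044 and 2012 CPM in rectal goblet-like and crypt-like cells and 496 CPM in rectal absorptive-like cells.

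Over whole libraries, the sums of the fixed lists differed between segments. The Paneth list summed to 4002, 6597, 50770, 118 and 145 CPM, and 12 of 14 members met the size rule on the small intestinal side. Ileum also led the goblet and mucus list, at 5526, 8012, 40660, 23880 and 12260 CPM, where 1 of 21 members met the rule. Posterior HOX genes, which mark the hindgut, summed to 2.54, 3.16, 17.4, 223 and 402 CPM, and 7 of 17 were higher in the large intestine. Extracellular matrix genes were higher where the stromal share was higher, at 309, 266, 301, 863 and 1699 CPM, with 2 of 19 higher in the large intestine. WNT and R-spondin genes summed to 25.7, 18.7, 19.5, 57.7 and 90.1 CPM, with 3 of 12 higher in the large and 1 in the small intestine. Sums for BMP genes were 51.8, 39.2, 68.5, 87.7 and 149, for niche ligands 638, 665, 357, 459 and 690, and for Notch and secretory fate genes 246, 199, 387, 551 and 452. MHC II and interferon genes summed to 6032, 7200, 6289, 2860 and 5849 CPM. Haemoglobin and other red cell genes summed to 0.297, 0.256, 6.52, 1.03 and 3.50 CPM, and none met the rule.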

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

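The tests of rectal AP-1 genes, their thresholds, and the count of other splits for the Gnai1 contrast were chosen only after the results were seen. A set of 4 genes drew attention because their goblet over absorptive folds lay on one side of 1 in every small intestinal library and on the other side in colon and rectum. The difference between the segments was not tested. Junb folds were 0.836, 0.722 and 0.779 in duodenum, jejunum and ileum and 2.03 and 4.07 in colon and rectum. Junb itself stood at 470, 443, 492, 404 and 645 CPM in goblet-like cells. In absorptive-like cells it stood at 562, 614, 632, 199 and 159. Maff folds were 0.638, 0.303 and 0.823 against 1.22 and 1.60. Its levels were 34.8, 16.3, 30.04, 21.4 and 37.5 CPM in goblet-like and 54.6, 53.98, 36.5, 17.6 and 23.5 in absorptive-like cells. Goblet-like levels of both genes thus overlapped between small and large intestine, whereas absorptive-like levels were lower in colon and rectum. Zfp36, which encodes a protein that destabilizes cytokine messages, had folds of 0.339, 0.355 and 0.320 against 2.23 and 4.32. Jund went the other way, at 1.41, 1.20 and 1.46 against 0.976 and 0.898. The intervals of Maff in ileum, colon and rectum and of Jund in colon reached 1, so their side there is uncertain from counting alone, and the rectal folds rest on 57 absorptive-like cells.

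AP-1 genes were highest in the rectum in crypt-like and goblet-like cells, where 9 and 8 of 10 list members led. The list summed to 9402 CPM in rectal crypt-like cells against at most 4681 elsewhere, and to 8526 against at most 6204 in goblet-like cells, though crypt-like and goblet-like cells of small intestine, colon and rectum lay in different clusters. A response shared by every rectal cell class to handling is argued against, since over 7 non-epithelial classes the rectal sum was a median of 0.919 times the highest other library, though B-like cells stood at 1.30 times and dendritic-like cells at 1.02, so a response of some classes stays open. A heat shock response is argued against as well, since 6 heat shock genes stood at 0.837 times the highest other library in goblet-like cells and 0.693 times in crypt-like cells. The 6 other immediate early genes did go with AP-1, at 1.27 times in goblet-like and 1.83 times in crypt-like cells, but not in absorptive-like cells, at 0.261 times (AP-1 0.666 times, 57 cells), so an acute response of rectal crypt-like and goblet-like cells may account for the pattern and stays open, as do a difference between these clusters and a difference between segments, which a single library each cannot test.

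For the Gnai1 contrast, 5 of 35 splits of the 8 sums into groups of 4 gave at least as many genes as the real 2. Each of these parted colon and rectum the same way by Gnai1, so each carries the real contrast of these 2 libraries. The count therefore cannot decide on chance, which is not excluded. The highest other count was 108 genes. It came from splits that left the sums of duodenum and of ileum unparted and are the same test with its sign reversed. They carry the contrast of the 2 large intestinal libraries alone and point to a structure of the samples. Only 8 splits part all 4 libraries as the design does, too few for a share under 0.05. Of these 3 gave at least 2 genes, the real one included, and the highest other gave 4. A further 3 of the 35 splits could not be fitted.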

How the results depend on the processing

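No paired analysis was possible because each segment has 1 library and the labels name no animal, so nothing pairs a library with that of another segment. Cell classes and the Gnai1 contrast were compared within libraries. Of 170 recalculations of main results 119 kept their direction and size, 49 moved and 2 reversed. Of 769 for single genes and shares 647 kept theirs, 105 moved, 11 lost their threshold and 6 reversed. The settings that leave out rectum, duodenum and jejunum, or the PDGFRA-high class, that of colon and rectum alone, that without defensin UMIs and that without Gnai1 in clustering were chosen after seeing the data. The cause was not tested unless stated. With at most 10% mitochondrial UMIs the goblet gap between large intestine and duodenum or jejunum turned from 26.5 to -15.5 percentage points, as the rectal cluster led by Sval1, Mptx1 and Best2 then stayed unnamed, which left a rectal share of 0.777%, while the jejunal share rose to 16.3% of the 178 epithelial cells left there. Jun goblet over absorptive folds turned to 1.43 in jejunum, 0.890 in colon and 0.601 in rectum, the stromal gap moved from 6.24 to 9.59 points, absorptive genes higher in large intestine fell to 109, goblet genes higher in small intestine to 12, and genes higher with Gnai1 to 0. With each library clustered on its own the ileal Paneth excess turned from 1.42 to -11.4 points, because 147 duodenal and 106 jejunal cells then took the Paneth name, and the goblet gap was 3.21. With Paneth and defensin genes left out of the UMI totals the Jun Paneth over absorptive folds turned from 0.593, 0.539 and 0.645 to 2.10, 2.32 and 2.90, and AP-1 genes lower in Paneth-like cells fell from 7 to 2, by construction of the totals. With every deposited barcode kept the stromal gap was 4.81, the goblet gaps 17.0 and 12.2, and 1 gene was higher with Gnai1. At least 1000 genes gave a goblet gap of 21.7 and 1 gene with Gnai1. With no doublets removed stromal Gnai1 was 72.0 CPM in colon and 121 in rectum, 5 stromal genes were higher in large intestine, and 8 genes were higher and 5 lower with Gnai1. Scrublet's own threshold gave 6 such stromal genes and 11 higher and 4 lower. A gap of 2-fold, looser by construction, gave 565 and 597 absorptive, 237 and 328 goblet, and 24 and 9 stromal genes. A minimum of 200 UMIs, stricter by construction, gave 162 absorptive genes in large intestine, 70 goblet genes in small intestine and 1 stromal gene. Removing genes whose share in immune cells exceeded 10% of that in the class gave 91 and 38 absorptive and 28 and 19 goblet genes. This is in part by construction, since a gene near 0 on its low side is easily removed. Without rectum 474 and 444 absorptive genes met the rule, and without duodenum and jejunum 301 goblet genes were higher in large intestine, as fewer libraries had to separate. In the Gnai1 contrast DESeq2 gave 6 higher and 2 lower, no filter 74 and 68, and colon and rectum only 238 and 304. Pairs matched within clusters gave 1 higher, and without the PDGFRA-high class 0 were higher. Leaving out 1 library gave 0 to 19 higher and 0 to 18 lower. The Benjamini-Hochberg adjusted p of Ogn in edgeR, 0.0378, ranged over the alternatives from 2.18e-17 in colon and rectum alone to 1.0 with pairs matched within clusters.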

Other observations

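The tests of epithelial Gnai1 and of interferon-stimulated genes, their thresholds and the list of 19 interferon-stimulated genes were chosen only after the results were seen. Enteroendocrine-like cells, which release hormones, held a Gnai1 UMI in 20 of 125 cells. By segment their level was 2.93, 18.9, 48.3, 5.29 and 2.71 CPM, and 21 of their 36 UMIs came from ileum. The AP-1 list was also higher in enteroendocrine-like cells of rectum, at 16690 CPM in 16 cells, than in those of the other segments, at 4319 to 6676 CPM.

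Among B-like cells a cluster led by the interferon-stimulated genes Ms4a4c, Ifi209, Ifi214 and Ifit3 held 31.7%, 22.9% and 30.7% of B-like cells in duodenum, jejunum and ileum, 1.24% in colon and 0 in rectum. Of the interferon-stimulated genes with enough UMIs 18 of 18 were higher in B-like cells of every small than of every large intestinal library. Among them Ifit3 stood at 165, 127, 176, 3.33 and 0 CPM and Irf7 at 108, 69.8, 113, 10.8 and 2.11. The whole list summed to 3427, 2169, 3653, 607 and 339 CPM. The same list summed to 1898, 1479, 3683, 395 and 486 CPM in absorptive-like cells and 2110, 959, 1693, 257 and 157 in goblet-like cells, with the lowest small at 3.04 and 3.73 times the highest large intestinal value. That ratio was 1.58 in enteroendocrine-like, 1.53 in ILC/NK-like, 1.36 in dendritic-like, 1.16 in T-like and 1.13 in crypt-like cells, and 0.982 in macrophage-like, 0.843 in fibroblast-like, 0.817 in plasma-like, 0.652 in smooth muscle-like, 0.625 in lymphatic endothelial-like and 0.554 in trophocyte-like cells.

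Gnai1 UMIs were found in 63 colonic and 126 rectal epithelial cells, or 5.60% and 16.0%, against 0.276%, 0.251% and 0.987% in duodenum, jejunum and ileum. The level was 1.67 and 10.9 CPM in goblet-like and 3.13 and 7.74 in crypt-like cells of colon and rectum, against 0.332 and 0 in absorptive-like cells (57 in rectum). Free RNA from stroma is argued against, since the ratio of Gnai1 to collagen and Dcn UMIs was at least 141 times that of stromal cells (interval 101 to 197 in colon). Doublets with stroma are argued against, since cells with a Gnai1 UMI held at most 0.0236% of the stromal level of fibroblast markers. Depth as the whole cause is argued against too. Median epithelial UMIs of colon and rectum were at most 0.799 times the highest small intestinal median. In ileum goblet-like and crypt-like cells had 0 Gnai1 UMIs among 6823407 and 6985830. Ileal goblet-like cells were deeper, at a median of 30986 UMIs against 26788 and 23895 in colon and rectum, whereas ileal crypt-like cells were shallower. Thinning to 1000 UMIs left too few to compare (0 of 1072 colonic, 5 of 739 rectal and 2 of 1040 ileal epithelial cells), and a difference between single libraries, a difference between segments and reads shared with related G alpha genes were not tested and stay open.

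For the interferon-stimulated genes of B-like cells, free RNA, which adds about alike to every droplet, is argued against as the whole cause of the sum, since UMIs of the list per ILC/NK-like cell were at most 0.581 times the small intestinal excess per B-like cell (upper bound 0.674). Among 18 members this held singly for 7, with Ifit3 and Ifi27l2a, and free RNA stays open for the others. A single abundant gene is argued against, since without Ifi27l2a the lowest small over the highest large intestinal value was 5.38, against 3.57 with it. A different mix of B-cell states is argued against for rectum, since in B-like cells clustered again without 201 genes of the list and of the interferon-led cluster the lowest small intestinal value was at least 2.59 times the rectal one (lower bound 1.85) in 8 of 9 clusters with 96.2% of rectal cells, but stays open for colon, where 2 clusters with 11.1% of its cells could be compared (3.43 and 7.70). Within the joint clusters, the comparison made first, the ratio was 1.13, 1.1 and 0.799 (8 colonic cells), which decides nothing because these genes help to define those clusters, while animals and days of processing cannot be separated from segments.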
